A study of Mus musculus with 6 samples.

How the data were processed

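The series holds 6 samples from mice of the C57BL/6 strain with allergic lung inflammation induced by house dust mite. They comprise 3 kinds of library for each of 2 genotypes, wild-type (WT) and Il9r-deficient (Il9r KO). The kinds are a transcriptome library, a library of antibody-derived tags (ADT, oligonucleotides on antibodies that report surface proteins) and a library of hashtag oligonucleotides (HTO, which mark the cell sample a cell came from). All 3 kinds of a genotype were made from the same loaded cells, so each genotype is represented by 1 pool, and the kinds of library are not replicates of one another. Groups were taken from the sample titles.

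Per the labels' protocols, lung macrophages positive for CD64 and MerTK and blood monocytes positive for CD115 were isolated by cell sorting, hashtagged separately and pooled within a genotype. The pools were loaded on a 10x Genomics Chromium instrument with version-3 reagents for sequencing of transcript 3' ends, at a higher than usual cell load. Cell Ranger 3.0.2, Seurat 3.1.0 and the genome build mm10 are named in the submitters' processing notes; the gene annotation release and the settings of cell calling are not given in the sources used here.

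The 4 deposited files analysed here are, for each genotype, a list of cell barcodes and a table of features (identifier, name and type). Their values are text: they hold no count, no sequencing depth and no antibody signal for any cell. Matrices of counts were not analysed here. The expression of Il9r, the comparison of KO with WT cells for genes, gene lists or cell classes, the shares of cell classes and the levels of the surface tags were all planned before the data were examined and were not computed. The rule for named genes written before the data were examined provides for this case: members of the fixed lists are reported as present in or absent from the feature table, and no gene is named for a level of expression. The planned filters on genes per cell and on mitochondrial reads need counts and were not applied, so every listed barcode was kept. Doublets were not called.

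Barcodes were counted per library, with exact Poisson 95% intervals. The ratio of KO to WT barcodes has an exact interval from the binomial share of KO barcodes. Shares have exact Clopper-Pearson intervals. All of these cover counting error only. With 1 pool per genotype they carry no information on variation between mice, and no p-value was computed. Barcodes present in both lists were counted, and pairs of barcodes that differ by 1 or 2 substitutions were counted within each library and between libraries. The between-library rate gave the number expected within a library, with a 95% interval from the Poisson errors of both counts. This step was tested on simulated data, with 2 libraries of 5000 random barcodes each. Into one of them 300 pairs were planted by adding barcodes 2 bases away from listed ones, and an excess of 301 pairs was found. Recovery over a background as large as the 2263 pairs expected in the KO library was not tested. Pairs 1 base apart were not planted.

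Features were compared between genotypes by identifier and by symbol. Gene classes and coordinates came from GENCODE mouse release M21, which is on the same build (mm10, also called GRCm38). Of 31053 gene identifiers, 30934 (99.62%) were found in that release and 119 were not. Of those found, 30468 had the same symbol in both, and the symbols of the rest differed. That release may therefore not be the one that the authors used. A total of 13 gene lists and 17 cell type marker lists, with 289 distinct genes (29 of them in more than 1 list), were fixed before the data were examined.

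For each gene of these lists, the last 500 bases of its transcripts in the basic set of the annotation were divided into all windows of 50 bases, leaving out transcripts annotated as incomplete at the 3' end. The share of distinct windows that also occurs, on the transcribed strand, in a transcript of another gene of the feature table was computed. The 119 genes of the table not found in the annotation could not be searched. Genes with a share of at least 50% are named. This step and its naming rule were chosen after the feature tables had been seen. Windows of 100 bases and the last 1000 bases were tried as alternatives. In a test on simulated data the script recovered the share for 40 of 40 genes, to within a few windows. These genes had a full, partial or no copy of their 3' end. Each had a single transcript and a single partner gene, so genes with several transcripts or partners were not tested. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used.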

Results

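The study profiled lung macrophages and blood monocytes from WT and Il9r KO mice with house dust mite-induced allergic lung inflammation. Il9r encodes the specific subunit of the receptor for interleukin 9, a cytokine of type 2 inflammation that signals together with the common gamma chain, encoded by Il2rg. Cells were characterised by cellular indexing of transcriptomes and epitopes (CITE-seq), in which transcripts and antibody tags are read from the same cell. The design addresses how loss of the interleukin 9 receptor alters lung macrophages and blood monocytes. It holds 1 pool per genotype, each with a transcriptome, an ADT and an HTO library. The lists of cell barcodes and of features were analysed, and transcript and tag levels were not analysed here. The results therefore describe the number of cell barcodes per genotype and the genes and proteins listed for counting, and give no level of expression.

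The first comparison concerned the number of cell barcodes listed per genotype. The WT pool contained 21074 cell barcodes (Poisson 95% interval 20790 to 21360) and the Il9r KO pool contained 22730 (22435 to 23027). The KO pool thus had 1656 more barcodes than the WT pool, a ratio of 1.079 (95% interval 1.059 to 1.099). Both exceeded the targeted recovery of 20000 cells per pool, reaching 105.4% of it in WT and 113.7% in KO. A barcode can stand for several cells, and doublets were not called, so these numbers are not exact counts of cells. The intervals cover counting error only, and whether the ratio exceeds the spread between mice or between loadings cannot be tested with 1 pool per genotype. Lung macrophages and blood monocytes were mixed before loading, so the number of barcodes is not a measure of cell abundance in lung or blood.

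The lists contained no repeated barcode within a library. A total of 156 barcode sequences occurred in both libraries, which is 0.740% of the WT barcodes (exact 95% interval 0.629 to 0.865%) and 0.686% of the KO barcodes (0.583 to 0.802%). The remaining barcodes were listed for 1 genotype each. The cells of a library cannot be divided into lung macrophages and blood monocytes from the barcodes alone, so shares of the 2 cell types are not given.

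The feature tables of both genotypes held the same 31057 features, listed in the same order, with 0 features differing. They comprised 31053 genes and 4 antibody features. Of the antibody features, 2 reported surface proteins. These were CD11c, the integrin encoded by Itgax, and SiglecF, a sialic acid-binding lectin encoded by Siglecf; alveolar macrophages typically carry both. The other two were hashtags, one for lung macrophages and one for blood monocytes. CD64, MerTK and CD115, the proteins used for sorting, had no antibody feature. Their genes Fcgr1, Mertk and Csf1r were in the gene table, as were Itgax and Siglecf, so CD11c and SiglecF were listed as both transcript and protein.

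Il9r (ENSMUSG00000020279), the gene inactivated in the KO mice, was in the feature table of both genotypes. It lies on the minus strand of chromosome 11 at 32187541 to 32200279 (mm10) and spans 12739 bp. The annotation gives it 5 transcripts, of which 3 are protein-coding. The principal transcript has 9 exons and 4482 bases. Its 3' untranslated region of 3071 bases lies in exon 9, at 32187541 to 32191046, which also holds the end of the coding sequence. No other annotated gene overlapped Il9r. The nearest neighbours were Gm12109, a processed pseudogene 1839 bp beyond its 3' end that was not in the feature table, and Snrnp25, a protein-coding gene 5135 bp beyond its 5' end that was. The part of Il9r that is altered in the KO mice is not given in the sources used here. Whether 3' transcript tags from exon 9 distinguish the genotypes therefore remains open.

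**Figure D1:**
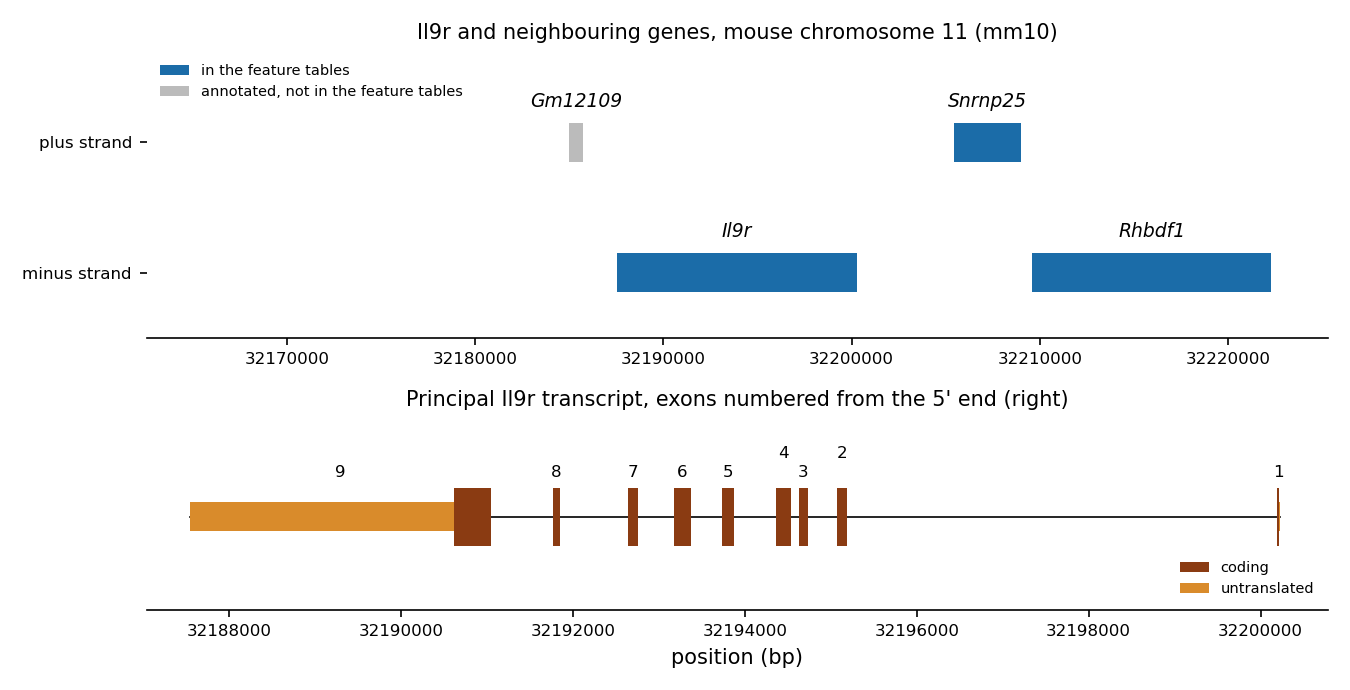
Map of the Il9r locus on mouse chromosome 11 (mm10; horizontal axes, position in bp). The upper panel shows annotated genes by strand, in blue where the feature tables list them and in grey where they do not; the lower panel shows the 9 exons of the principal Il9r transcript, with coding parts tall and untranslated parts short. No other gene overlaps Il9r, and exon 9 holds the 3' untranslated region of 3071 bases.

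Each of the 289 distinct genes of the 30 fixed lists was in the feature table, and 0 were absent. The table names the genes on which reads could be counted, whether or not any were detected, so presence in it says nothing of expression in these cells. The 17 genes of alternative activation, the macrophage state linked to type 2 cytokines, included the arginine-degrading enzyme gene Arg1. The 20 chemokine genes included Ccl5, which encodes a chemoattractant for T cells and eosinophils. The 20 genes of common gamma chain receptors and STAT feedback included Il9r and Il2rg. Marker lists for the sorted populations were likewise listed in full, with 14 genes for alveolar macrophages, 14 for interstitial macrophages, 10 for classical monocytes and 12 for nonclassical monocytes. Markers of cells that a sort of this kind can carry along were also listed in full, including 9 for neutrophils, 6 for eosinophils and 10 for dendritic cells. The glycolytic gene Aldoa was the only list member that appeared under more than 1 identifier. Its 2 entries lay side by side on the minus strand of chromosome 7, at 126795234 to 126800751 and at 126800790 to 126809108. Among all genes, 35 symbols were shared by 71 identifiers.

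The feature table covered some gene classes almost completely and others hardly at all. It held 21897 of the 21951 protein-coding genes of the annotation (99.8%), 5459 of 5854 long intergenic non-coding RNA genes (93.3%) and 2816 of 2959 antisense genes (95.2%). It also held 694 of 702 immunoglobulin and T cell receptor segments (98.9%), which include markers of B and T cells. By contrast, 40 of 13315 pseudogenes outside these receptor loci (0.3%) and 0 of 6084 small RNA genes were listed. From the mitochondrial genome, 13 genes were listed, while 0 of 2 ribosomal RNA genes and 0 of 22 transfer RNA genes were. Gene classes refer to the 30934 identifiers found in the annotation.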

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

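The number of barcodes common to both libraries was 156 with or without the barcode's suffix, and the gene lists of the genotypes were identical by identifier (31053 genes) and by symbol (31017 distinct symbols). Neither alternative could have given another result. Every barcode of both libraries carried the same suffix, and the feature tables were the same row by row. The count of list genes that share at least 50% of their 3' end with other genes of the feature table was 7. It was 5 with windows of 100 bases, without Eno1 and Oas1a, and 7, the same genes, with the last 1000 bases; these alternatives were chosen after seeing the data. Other settings of the cell filter, normalisation, minimum counts, averaging over cells, doublets and clustering, chosen before the data were examined, were not run, since each needs counts per cell. No paired analysis was possible because each genotype has 1 pool and no test was made. The number of barcodes sets only the counting error of the comparison of barcode numbers. The spread between pools, which also limits that comparison, is unknown with 1 pool per genotype. Sequencing depth, on which any statement on expression depends, is unknown from the lists.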

Other observations

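The test of barcode pairs and the search of 3' ends were chosen after the lists had been seen. For most genes of the fixed lists, no window of the 3' end occurred in another gene of the feature table. Only exact matches were counted, and genes outside the table were not searched. Nor were the 119 genes of the table that were not found in the annotation. The table held 40 of 13315 pseudogenes outside the immunoglobulin and T cell receptor loci, so copies in other pseudogenes would be missed. Of the 290 gene identifiers behind the lists, 250 shared 0 of their 50-base windows with another gene of the feature table, among them Il9r, Arg1 and Ccl5. A further 33 shared some but less than 50%, and 7 shared at least 50%. The number with some but less than 50% was 13 with windows of 100 bases and 51 with the last 1000 bases, and the number with 0 was 272 and 232. Of the 4 genes of the erythroid list, picked out after the values were seen, 3 were among these 7. Each of the 3 shared its windows with another globin gene. Hba-a1, an alpha-globin gene, shared 88.9% of its windows with Hba-a2, and the beta-globin genes Hbb-bs and Hbb-bt shared 64.7% and 64.5% with each other. Gapdh, a glycolytic enzyme gene often used as a reference, shared 85.8%, mostly with Gm10358. Eno1, another glycolytic gene, shared 75.5% with Eno1b. The interferon-induced gene Oas1a shared 56.1% with Oas1g. The complement gene Cfb shared 83.6% with Gm20547, which overlaps it on the same strand. For the other 6, the main partner did not overlap the gene on the same strand. How far away it lies was not examined. With windows of 100 bases the shares of Eno1 and Oas1a were 47.9% and 40.9%, below 50%, and the other 5 genes remained above it. Reads that lie wholly within such shared stretches cannot be assigned to 1 of the genes by sequence, and how many reads do so depends on their length, which is not given in the sources used here.

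Several markers of the sorted populations shared a smaller part of their 3' end. These genes were picked after their values were seen. Ceacam1, a nonclassical monocyte marker, shared 46.0% with Ceacam2. Ear2, an alveolar macrophage marker, shared 38.1%, mainly with Ear1, although Ear10 was its main partner with windows of 100 bases and with the last 1000 bases. Ly6c2, the classical monocyte marker, shared 34.8%, mainly with Ly6c1. Chil3 and Chil4, chitinase-like genes of alternative activation, each shared 17.1%. Jak3, the kinase that binds the common gamma chain, shared 41.5% with Insl3, which overlaps it on the same strand. With windows of 100 bases the shares of Ceacam1, Ear2, Ly6c2, Chil3 and Jak3 were 32.2%, 6.5%, 16.7%, 6.7% and 37.9%. With the last 1000 bases they were 46.0%, 37.6%, 31.2%, 14.2% and 26.2%. Il2rg, the common gamma chain gene, shared 0 windows in the last 500 bases and 38.3% in the last 1000 bases, with Gm20489, which overlaps it on the same strand. The share of Il9r in the last 1000 bases was 0.3%.

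The KO library listed 1656 more barcodes than the WT library. A hypothesis was that some KO cells were listed again under a barcode 1 or 2 bases away. Within the KO library, such pairs exceeded the 2263 expected from the between-library rate by 53 (95% interval -63 to 170), and within the WT library they differed from the 1945 expected by -25 (-129 to 79). The upper bound of 170 lies far below 1656, which argues against this as the source of the gap. Between the libraries, 4196 pairs differed at 2 bases and 0 at 1 base, so the test rests on pairs 2 bases apart. Loading, cell calling and depth may differ between the pools; the lists record none of them, and they stay open, as does the genotype, which was not tested and coincides with the pool.

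Pairs that differ at 1 base were found in the KO library alone. There were 3 of them, all differing at the last base, against 0 in the WT library and 0 between the libraries. If every barcode sequence were equally available to both pools, 156 barcodes in common would correspond to a set of 3070000 available sequences (2620000 to 3620000 from the Poisson interval, rounded). The supplier's list of sequences was not used here.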
